A study of Rattus norvegicus with 6 samples.

How the data were processed

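Small RNAs were measured in islets of 3 P10 samples (10 days of age, 2 pups pooled per sample) and 3 adult samples (3 months, single animals). Per the labels' protocols, total RNA was labelled at the 3′ end with the dye Cy3 by RNA ligase and hybridised to 1-colour piRNA arrays, so that each array reads 1 sample. Ligation labels any RNA with a free 3′ end, and a probe reads whatever labelled RNA binds to it. Groups and replicate numbers were taken from the sample titles.

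Per the file headers, the spot intensity values deposited by the authors were written by Agilent Feature Extraction 11.0.1.1, with the background subtracted and with no normalization between arrays. Each array held 42734 spots, of which 1417 were control spots and were left out. The remaining 39886 probes were 39727 piRNA probes with 1 spot each and 159 probes for transcripts, miRNAs and unnamed custom sequences with 10 spots each. The deposited value table holds log2 values of 18540 piRNA probes. Its columns have a median of 3.66 and nearly equal highest values, as quantile normalization gives, and rank correlations with the scanner signal of the same array between 0.979 and 0.998. Its normalization software is not given in the sources used here, and its direction and log2 scale were read from the header of the comparison table, which holds the same numbers. The 18540 probes are those well above background on at least 1 array, as tested on the files. In the authors' deposited table of changed piRNAs, the p-value is that of an unpaired t-test with no adjustment and the fold is a ratio of group means, per the file headers. No column of per-sample values was left unused.

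The slide of each array was read from the scan identifiers. Slide 1 held the 3 P10 arrays and Adult 1, and slide 2 held Adult 2 and Adult 3, so age and slide overlap in part. Median local background was between 19 and 21 on all arrays. The 75th percentile of the processed signal over detected piRNA probes was 175, 95.7 and 140 in P10 1, P10 2 and P10 3 and 139, 108 and 101 in Adult 1, Adult 2 and Adult 3. No spot was saturated, and between 82 and 154 spots per array carried an outlier mark and were left out.

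Levels are log2 of the processed signal minus the 75th percentile of each array over piRNA probes well above background on all 6 arrays, because under 50% of piRNA probes were well above background on every array (between 27.6% and 36.7%). A level therefore states brightness relative to the other detected probes of its array, not an amount of RNA per islet, and levels of different probes are not compared as amounts. Spots of 1 probe were averaged on the log2 scale. Probes well above background on all 3 arrays of at least 1 age were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, adult minus P10, two-sided), with Benjamini-Hochberg adjustment over piRNA probes and a threshold of 0.05. The 159 other probes were tested with the same scaling and adjusted among themselves, a choice made after their number was known. Figures were drawn with matplotlib 3.10.9. A named probe not well above background on every array of its dimmer age has only a bound there. It is given as the mean of the brighter age against the mean of the dimmer one, in which each undetected array takes the higher of the probe's own signal and the array's lowest signal among detected probes.

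Of 89 transcript probes, 61 matched 38 genes in a RefSeq gene table of the assembly GRCr8 through their transcript identifiers. The others keep the name in the files. Where a gene has several probes, each is reported. Gene lists were fixed before the data were examined as lists of genes that host piRNAs. Without sequences or positions they could be applied only to the transcript probes, as gene lists, with camera (preset correlation of 0.01) for lists with at least 5 tested probes. Lists by first base, length, genome matches, annotation and genomic run need sequences or a genome and were not analysed here. Named piRNA probes were chosen by a rule set before the data were examined. It takes the 12 largest differences in each direction among called probes with 3 values per age whose ages do not overlap, the 3 largest called members of each list past the threshold (no list passed it), the called member of each list with the largest difference (none was called), DQ732700 and DQ746748, and the 3 brightest tested probes of each age. The part of the rule that keeps 1 probe per genomic run could not be applied.

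The fit was tested on simulated data for the adult versus P10 comparison, with 11766 probes at their measured means and residual SDs and 200 probes changed by known folds. Of the probes changed 2-fold, 4-fold, 8-fold and 16-fold, 0%, 38%, 68% and 86% were called, with 9 false calls. The simulation held no slide effect and no array lying between the ages. It changed 200 of 11766 probes, whereas in the data 3342 of 11900 had an unadjusted p below 0.05 (limma). The shares called under Benjamini-Hochberg adjustment depend on how many probes change, so they need not carry over to the data. Array brightness was also tested as the cause of the position of P10 1 and Adult 1 between the ages. That test was left out of the closing section to keep to 3 kinds of explanation, after its result was seen. P10 3 and Adult 1 had nearly the same 75th percentile (140 and 139) but lay at -90.2 and 15.1 on the first principal component. These 2 arrays differ in age, so the comparison cannot decide the question. Within each age, P10 1 (175, against 95.7 and 140) and Adult 1 (139, against 108 and 101) were the brightest arrays, so brightness stays open as a cause. Alternatives covered the normalization between arrays, background correction, the filter on dim probes, the deposited value table, the variance model, array weights, the methods' t-test, the replicate number and the slide as a block, and leaving out each array. Normexp was planned on mean signals and was run on median signals, because the files hold no mean signal column. It added an offset of 50 to every signal. This offset, like the background left in without correction, shrinks log2 differences of dim probes by construction. Taking the median over spots moves no piRNA probe, which has 1 spot.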

Results

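Islets of the rat pancreas, the endocrine clusters that hold the insulin-secreting beta cells, were profiled on arrays carrying probes for PIWI-interacting RNAs (piRNAs), a class of small RNAs best known from the germline. RNA came from pups at postnatal day 10 (P10, 10 days of age) and from adults of 3 months. Each of the 3 P10 samples pooled the islets of 2 pups, whereas the 3 adult samples were extracted from single animals, so each array is a separate biological sample and their number limits the precision. The comparison asks which piRNAs differ in level between islets of newborn rats, whose beta cells are still maturing, and islets of adults. The probes are named here by the piRNA entries they carry. Their sequences and genomic positions are not given in the sources used here, so no chromosome, gene or exon is stated for them.

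Of 39727 piRNA probes, 14598 were well above background in P10 1, 12033 in P10 2 and 14238 in P10 3, against 14236 in Adult 1, 10964 in Adult 2 and 12139 in Adult 3. The mean difference, adult minus P10, was -1177 probes (between -2072 and -436 with 1 array left out) and lay within the spread between arrays (exact permutation test, two-sided, p = 0.4, where 0.1 is the smallest p that 3 against 3 arrays allow). Within slide 1, which held all 3 P10 arrays and Adult 1, the adult value lay inside the range of the P10 values; slide 2 held adult arrays only. In all, 8874 probes were well above background on all 6 arrays, and the 11911 that were so on all 3 arrays of at least 1 age were tested.

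The arrays did not fall into compact groups by age. Across tested probes, P10 2 and P10 3 correlated at r = 0.948 and Adult 2 and Adult 3 at r = 0.972. P10 1 correlated more closely with Adult 1 (r = 0.940) than with P10 2 (0.888) or P10 3 (0.906), and Adult 1 more closely with P10 1 than with Adult 2 (0.916) or Adult 3 (0.908). These correlations are across probes, which are not independent replicates.

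**Figure D1:**
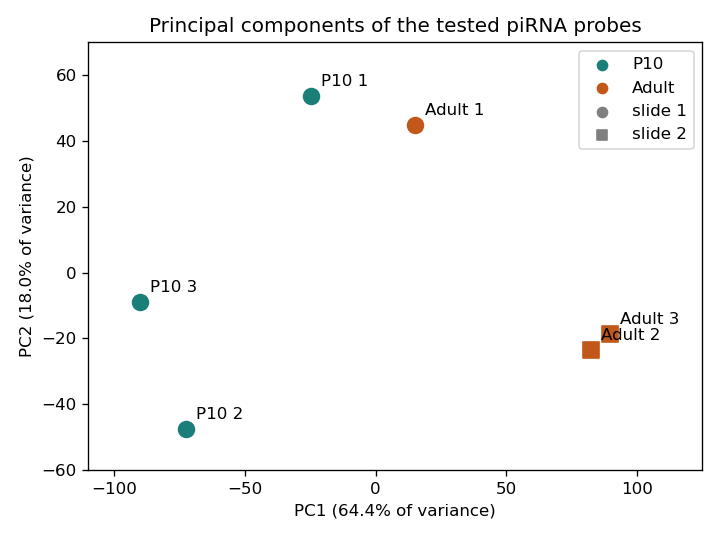
First and second principal components (arbitrary units, with the percent of variance) of log2 signals of 11766 tested piRNA probes with 6 values; each point is 1 array, coloured by age, with circles for slide 1 and squares for slide 2. P10 1 and Adult 1 lie between the other P10 arrays at the left and Adult 2 and Adult 3 at the right.

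In adult islets 496 piRNA probes were higher and 207 were lower than in P10 islets (limma, Benjamini-Hochberg threshold of 0.05, 3 arrays per age). The counts depended on the processing: cyclic loess left 1 higher and 0 lower, and looser detection filters left 0 and 0. With cyclic loess 3354 probes still had an unadjusted p below 0.05 (limma). Normexp background correction, with an offset of 50, gave 17 and 49, with the balance turned. Under it the median difference of all probes moved to 0.31 on the log2 scale. In the main fit the median difference of the called probes was 5.29-fold for those higher and 4.65-fold for those lower in adult. Every one of the 703 differed at least 2-fold as measured. Of these, 317 higher and 97 lower were well above background on all 6 arrays, with medians of 5.11-fold and 4.22-fold. Over all 11900 probes with a p-value the median difference was -0.04 on the log2 scale, and 3342 had an unadjusted p below 0.05 where chance gives 595 on average. The 9 other splits of the arrays into 3 and 3 gave between 19 and 1551 such probes. In 3731 probes (31.4%) all values of 1 age lay above all values of the other, where chance gives 10%. All calls were marginal: the lowest adjusted p over the tested probes was 0.037.

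**Figure D2:**
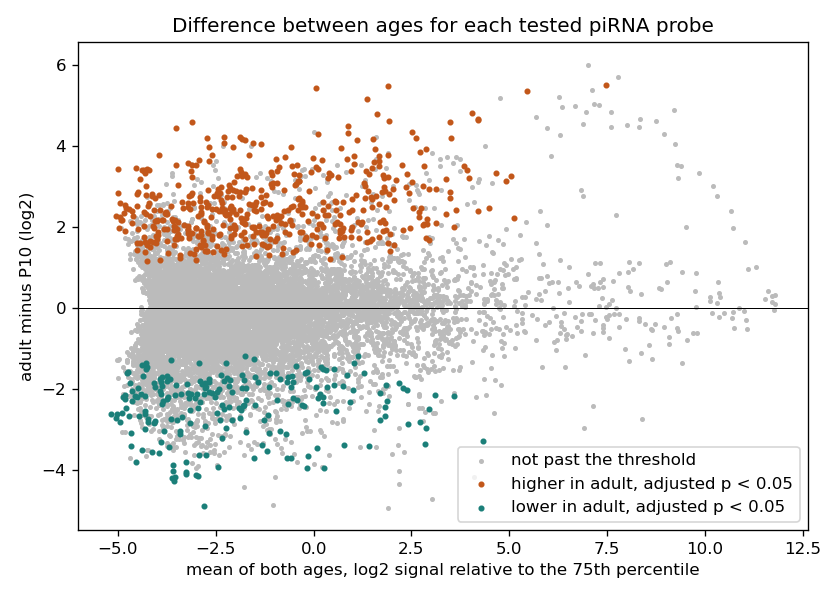
Difference between ages (adult minus P10, log2) against the mean level of both ages (log2 signal relative to the array's 75th percentile); each point is 1 tested piRNA probe. The 496 probes called higher and the 207 called lower in adult are coloured, and some bright probes with differences of over 4 on the log2 scale are not past the threshold.

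The 12 named increases are the largest as measured among called probes with 3 values per age and all adult values above all P10 values. The 9 of them well above background on every array lay between 22.4-fold and 44.3-fold. Their log2 differences, between 4.49 and 5.47, moved to between 2.38 and 4.53 with normexp, where DQ736839 was no longer called, and spanned 3.79 to 6.66 over the fits with 1 array left out. Among these 9, DQ605460 rose most, by 5.47 ± 0.63 on the log2 scale (SE), from -0.85 ± 1.35 in P10 to 4.62 ± 0.26 in adult islets (SD, n = 3 each; level relative to the array's 75th percentile; limma adjusted p = 0.037). DQ608895 was at 8.12 ± 0.43 in adult islets against 2.78 ± 2.29 in P10 (SD, n = 3; limma adjusted p = 0.043). DQ622874 and DQ622875, which are consecutive entries, rose by 5.17 ± 0.82 and 4.79 ± 0.96 (SE). DQ733848 rose by 4.81 ± 0.96, DQ620900 by 4.68 ± 0.91, DQ762218 by 4.64 ± 0.86, DQ614314 by 4.62 ± 0.63 and DQ736839 by 4.49 ± 1.03. The other 3 were above background on only 2 (DQ735263) or 1 (DQ741738 and DQ611982) of the P10 arrays. On background-subtracted signals they were at least 39.0-fold, 11.5-fold and 8.28-fold higher in adult islets, with undetected arrays set at the lowest signal among detected probes where the probe lay below it. These bounds did not hold under other background handling, with log2 differences of 2.70, 1.12 and 0.95 with normexp and 4.08, 1.86 and 1.46 without correction. Both settings shrink differences of dim probes by construction. The P10 arrays spread more than the adult arrays, with a median SD of 1.84 against 0.45, and P10 1 was the highest P10 array in all 12.

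The 12 named decreases, chosen in the same way, lay mostly in probes that were near background in adult islets, where the measured size and order have little meaning. DQ749464, the only one of them well above background on all 3 adult arrays, fell by 3.94 ± 0.73 on the log2 scale (SE), from 1.79 ± 0.51 in P10 to -2.15 ± 1.54 in adult islets (SD, n = 3 each; limma adjusted p = 0.043). Its difference was -2.20 within slide 1 and with the slide as a block, -2.14 with normexp and -4.81 without Adult 1, and it was not called with the slide as a block. For 9 others, only 1 adult array was well above background, and with the undetected arrays set at that lowest signal only a bound on the decrease of the background-subtracted signal is given. DQ626327 was at least 10.7-fold lower in adult islets, DQ626858 at least 8.56-fold, DQ754744 at least 8.17-fold, DQ614553 at least 7.87-fold and DQ604390 at least 7.31-fold. DQ753714 was at least 6.86-fold, DQ738077 at least 6.61-fold, DQ747392 at least 6.34-fold and DQ740304 at least 5.27-fold lower. DQ762651 and DQ760389 were not well above background on any adult array and were at least 6.68-fold and at least 3.24-fold lower by the same measure (limma adjusted p = 0.043 and 0.049). Not all of these bounds held within slide 1, and none did under other background handling: the 12 decreases had a median of -2.82 on the log2 scale within slide 1, -0.39 with normexp and -1.51 without correction, against -4.10 as measured. DQ626327 was at -0.93 and -2.14, DQ762651 at -0.29 and -1.43, and DQ760389 turned to 0.07 with normexp and was at -0.84 without correction. Both settings shrink differences of dim probes by construction, and with normexp the median of all tested probes was 0.31. Adult 1 was the highest adult array in 11 of the 12. In all, 51 of the 207 probes called lower were not well above background on any adult array, and 47 of the 496 called higher were not so on any P10 array.

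**Figure D3:**
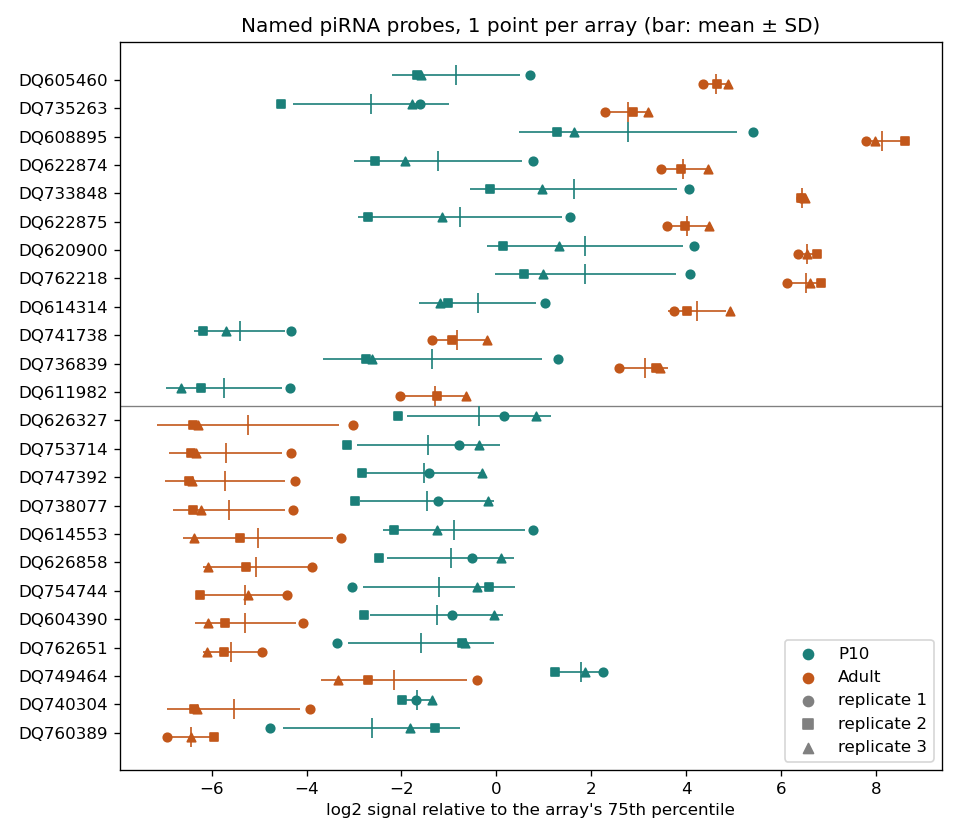
Level of each of the 24 named piRNA probes (log2 signal relative to the array's 75th percentile), with 1 point per array and a bar for the mean ± SD of each age; the 12 above the line were higher and the 12 below it lower in adult. In the upper probes P10 1 is the P10 array nearest to the adult values, and in 11 of the lower ones Adult 1 is the adult array nearest to the P10 values.

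The number of calls rested on single arrays. Without P10 2, P10 3, Adult 2 or Adult 3 the named increases kept medians between 4.20 and 4.77 on the log2 scale. The named decreases, mostly near background in adult islets, kept medians between -4.78 and -3.64. The named probes were chosen on these same arrays, so their sizes are no separate test. Leaving out P10 2, P10 3, Adult 2 or Adult 3 left 0 calls each, whereas leaving out P10 1 gave 1767 and leaving out Adult 1 gave 2058, and with both left out, as chosen after seeing the data, 3614 probes were called, 1489 higher and 2125 lower, including 702 of the 703. With the slide as a block 1 probe was called, DQ750471, which is not among the 703 and owed this to a single bright spot on Adult 1, and 1348 probes had an unadjusted p below 0.05. Within slide 1, where the age difference is Adult 1 against 3 P10 arrays, the calls higher in adult had a median of 1.97 on the log2 scale, against 2.58 for Adult 2 and Adult 3 versus the same P10 arrays. For the calls lower in adult the corresponding medians were -1.83 and -2.39. The probes were called with these same arrays, so their direction within slide 1 is no separate test of the calls.

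DQ732700 and DQ746748, which the study is known to have followed up, were not called, and neither is in the authors' deposited table of changed piRNAs. DQ732700 had an adult minus P10 difference of -2.54 ± 0.93 (SE; limma adjusted p = 0.128), with P10 values of -1.68 in P10 1 and 2.16 in P10 2, and passed the threshold with array weights, without P10 1 and without both arrays numbered 1 (limma adjusted p = 0.036, 0.023 and 0.022). DQ746748 differed by 0.07 ± 0.33 (limma adjusted p = 0.909). None of the 6 brightest tested probes passed the threshold with all arrays at equal weight. In adult islets these were DQ602399 (11.95 ± 0.19, SD, n = 3), DQ602400 (11.87 ± 0.32) and DQ609222 (11.86 ± 0.20), and in P10 islets DQ762484 (11.80 ± 0.38), DQ617231 (11.73 ± 0.25) and DQ617460 (11.63 ± 0.30). Of these 6, DQ609222 alone differed by over 1 on the log2 scale, at 2.40 ± 0.78 (SE; limma adjusted p = 0.096), and it passed with array weights, without P10 1 and without both arrays numbered 1 (limma adjusted p = 0.0069, 0.0037 and 0.0026).

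The array also carried 159 probes for other RNAs, each printed as 10 spots. Of 83 tested, 6 were higher and 0 lower in adult islets after adjustment over these probes (limma), and 20 had an unadjusted p below 0.05. All 6 are named here because there are so few, after their values were seen. P2rx2, an ATP-gated cation channel, rose by 3.28 ± 0.62 (SE; limma adjusted p = 0.026). For Pgk1, a glycolytic enzyme, 1 probe rose by 3.55 ± 0.74 (limma adjusted p = 0.034), while another probe of the gene gave 0.21 ± 0.29. The remaining tested probe, detected on only 1 of the adult arrays, changed sign with the processing. A probe for the mouse miRNA miR-770-3p rose by 1.59 ± 0.35 (limma adjusted p = 0.035). The virus miRNA probes mghv-miR-M1-3 and ebv-miR-BART6-3p rose by 2.50 ± 0.46 and 1.96 ± 0.36 (both limma adjusted p = 0.026). The transcript probe A_44_P480605, which had no gene match, rose by 1.70 ± 0.39 (limma adjusted p = 0.038). Each was higher in 3 of 3 adult arrays than in any P10 array and kept its direction, but not its size, under every scaling tried. P2rx2 lay between 1.31 and 3.38 and the Pgk1 probe between 1.95 and 3.65. With normexp 2 of the 6 were called, along with 3 probes lower in adult, and with quantile normalization 5. On slide 1 alone, where Adult 1 is the only adult array, all 6 stayed higher in adult, between 0.998 (miR-770-3p) and 3.37 (P2rx2) on the log2 scale. Since Adult 1 lay above every P10 array in each of the 6, this direction is no separate test. Leaving out P10 2, P10 3, Adult 2 or Adult 3 ended all 6 calls. Without P10 1 there were 7 higher and 1 lower, and without Adult 1 there were 6 higher and 11 lower (limma).

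**Figure D4:**
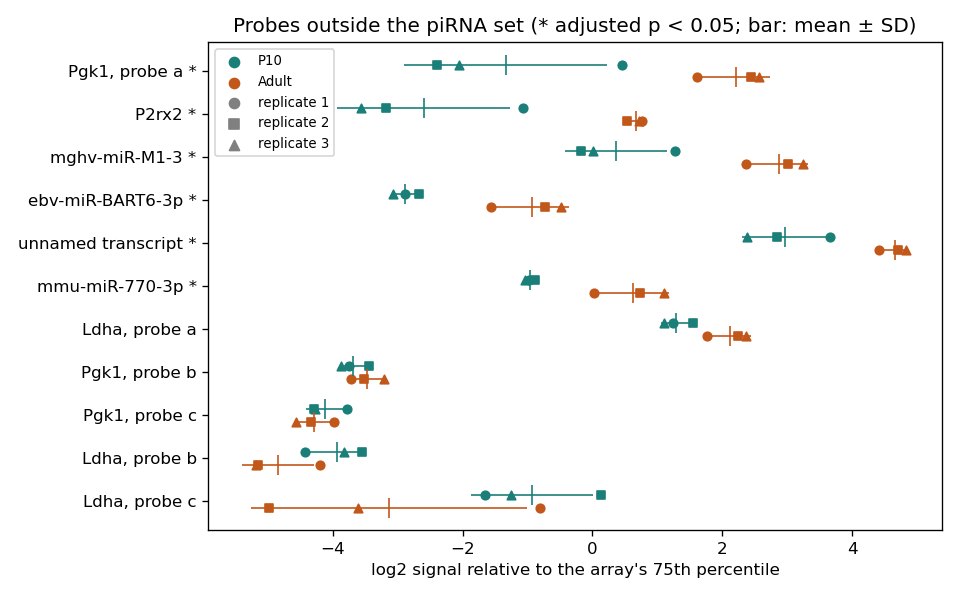
Level of probes outside the piRNA set (log2 signal relative to the array's 75th percentile, mean of 10 spots), with 1 point per array and a bar for the mean ± SD of each age; an asterisk marks adjusted p below 0.05. All 6 marked probes are higher in adult islets, and the probes of Pgk1 and of Ldha differ from each other.

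Of the gene lists fixed for islets, few had members on the array. Genes of endocrine, acinar, ductal, endothelial and stromal, blood and immune cells, of imprinted loci, proliferation, the piRNA pathway, histones and snoRNA hosts had 0 probes, so the make-up of the islet preparations was not measured here. Ldha, a lactate dehydrogenase subunit kept low in adult beta cells, was the only member of the list of immature or disallowed genes. Of its 3 tested probes, the 1 detected on every array gave an adult minus P10 difference of 0.83 ± 0.31 (SE). The other 2, detected on 2 and 1 of the adult arrays, were lower in adult islets, but 1 turned positive on slide 1 alone and the other with normexp, and no size is given for them. None was called over all probes or adjusted over the list alone (limma), and 1 had an unadjusted p below 0.05. The 6 probes of the ribosomal protein genes Rplp1 and Rpl13a had a median difference of -0.36 (limma's camera with its preset correlation, p = 0.221; p = 0.589 with an estimated correlation). Of these 6 probes 0 were called over all probes or adjusted over the list alone (limma), and 0 had an unadjusted p below 0.05.

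The authors' deposited table lists 1791 piRNA probes as changed, 1056 higher and 735 lower in adult, at an unadjusted p of at most 0.05 and at least 2-fold. It comes from the same arrays and is not independent. Of the 1768 probes tested here, 99.9% had the same direction, 669 passed the adjusted threshold, and log2 differences correlated at r = 0.988 across probes. Applied to the deposited value table, the same kind of test gave the same 1056 and 735 probes. After Benjamini-Hochberg adjustment 1 probe of that table passed, and 2826 had an unadjusted p below 0.05 where chance gives 927.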

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

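The comparison of the share of foreign probes with that of piRNA probes was chosen after the signals below were seen. The test over repeated spots was set before.

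Signals outside the piRNA measurement were found in probes for miRNAs of organisms other than mammals. Of 27 probes for miRNAs of plants, worms and viruses, 19 were above background on no array and 8 on all 6. The mean processed signal over the arrays was 12550 for ppt-miR535a, a moss miRNA, with values between 4314 and 35879 per array. It was 531 for mghv-miR-M1-3, 359 for mcmv-miR-m01-1, 344 for mcmv-miR-M87-1 and 316 for ebv-miR-BART17-5p. It was 81.4 for mdv2-miR-M30, 40.0 for ebv-miR-BART6-3p and 19.7 for cel-miR-49. Among transcript probes, which the piRNA comparison does not use, 58 were above background on all 6 arrays.

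Two-sided Fisher's exact test found no difference between the share of foreign probes above background on all 6 arrays, 29.6% (exact 95% interval 13.8% to 50.2%), and that of piRNA probes, 22.3% (p = 0.358). A share this high among probes with no target in the rat is what cross-hybridization of labelled rat RNA could give, and it may also place some piRNA probes above background, though 27 probes leave a wide interval. The shares are also not fully alike. Detection of a foreign probe drew on its 10 spots, whereas a piRNA probe has 1 spot, which counted as undetected if it carried an outlier mark. Local defects or bright neighbouring spots are argued against, since the 10 spots of a foreign probe on an array had a median SD of 0.137 on the log2 scale. Control RNA added to the samples, which the sources used here do not describe, stays open. Age is also open as a biological difference, as 2 of the 8 probes were higher in adult islets, and it was not tested which RNA binds them.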

How the results depend on the processing

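Normexp, the uncorrected median signal, 1 probe per run, all probes in 1 fit, slide 1 alone, leaving out both arrays numbered 1 and normexp with an estimated correlation were chosen after seeing the data. The main counts were 496 higher and 207 lower in adult islets, and causes of the moves below were not tested unless stated. Calls came to 328 and 118 with median centring, 1 (DQ749854, named after its values were seen) and 0 with cyclic loess, 17 and 49 with normexp, and 1853 and 2405 with array weights, which were lowest for Adult 1 (0.42) and P10 1 (0.43). They came to 0 and 0 without a filter on dim probes (5137 at an unadjusted p below 0.05), and to 0 and 0 with detection on at least 1 array (3674), where more probes are adjusted for. The methods' t-test gave 1036 and 759 at its own threshold and 0 and 0 after Benjamini-Hochberg adjustment (2612 at an unadjusted p below 0.05). With the slide as a block, and on slide 1 alone, there were 1 and 0, with 1 adult array left against 3. With 1 probe per run there were 233 and 97 among fewer probes, and without both arrays numbered 1 there were 1489 and 2125. Leaving out 1 array gave between 0 and 1030 higher and between 0 and 1173 lower calls, and between 0 and 1116 or, without Adult 1, 1282 probes of the authors' deposited table past the threshold; the 0 counts are those without P10 2, P10 3, Adult 2 or Adult 3 (2160 to 2759 at an unadjusted p below 0.05). Normexp moved the median difference of all probes to 0.31.

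Deviations of same-numbered samples from the mean of their age correlated at -0.036, 0.243 and -0.230, and those of P10 1 and P10 3 correlated best with another number. Replicate numbers thus gave no sign of a general pairing. The check cannot rule out something shared by P10 1 and Adult 1, since their deviations point toward each other's age. Their levels correlated at r = 0.940, the highest value between ages. With the replicate number as a block 0 and 0 probes were called by limma, and 3175 had an unadjusted p below 0.05.

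All 24 named calls kept their direction under every alternative that gave them a value, except DQ760389, at 0.067 with normexp. Detection on all 6 arrays gave a value for 10 of them, and 1 probe per run for 19. The sizes of the lower named calls did not hold under other background handling or within slide 1. The 12 lower ones had a median of -0.39 with normexp, -1.51 without correction and -2.82 with the slide as a block or on slide 1 alone, against -4.10 as measured. For the 12 higher ones these medians were 3.18, 4.39 and 4.43 against 4.73. The lowest of these 12 was at 0.95 with normexp and 1.46 without correction, against 4.44 as measured. These settings shrink differences of dim probes by construction. With cyclic loess the medians were -4.03 for the lower and 4.65 for the higher ones. Of the 24, 10 were past the threshold with normexp, 17 without correction and 0 with cyclic loess, either block, looser filters, the adjusted t-test or slide 1 alone. DQ732700 and DQ609222, uncalled with all arrays at equal weight, passed it with array weights, without P10 1 and without both arrays numbered 1. Uncalled probes near 0 changed sign. DQ746748 was at -0.17 without both arrays numbered 1 and between -0.11 and 0.34 over the fits with 1 array left out, negative without P10 1 or P10 3. With normexp DQ602399, DQ602400, DQ617231 and DQ617460 were at -0.32, -0.32, -0.47 and -0.43. DQ602400, DQ617231 and DQ617460 were at -0.035, -0.27 and -0.28 with quantile normalization and at -0.035, -0.22 and -0.28 in the value table. With cyclic loess DQ617231 and DQ617460 were at -0.11 and -0.054. With the slide as a block, and on slide 1 alone, DQ602400 was at -0.053 and DQ617460 at -0.075. DQ762484 was at 0.0087 with median centring, 0.050 with the percentile over all piRNA probes, 0.035 with array weights and between -0.18 and 0.16 over the fits with 1 array left out, positive without P10 2. DQ617231 was between -0.044 and 0.29 over those fits, negative without P10 3 or Adult 1.

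The ribosomal protein probes had a median of -0.35 with normexp, the only alternative under which the list passed the threshold (limma camera adjusted p = 0.0019, the same as unadjusted, as no other list had 5 tested probes). The list itself barely moved from -0.36, while the median of all tested probes, with which camera compares it, moved from -0.039 to 0.31. That call also rests on camera's preset correlation. With the correlation estimated from the data p was 0.112 (limma camera adjusted p, 1 list). The difference in detected probes kept its sign under every alternative. Signal over background limits the decreases, since 51 of the 207 probes called lower were not well above background on any adult array.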

Other observations

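The counts of bright probes, the values on the arrays numbered 1, the test of the slide and that of chance over accession numbers were chosen after the data were seen; the other tests were set before their results.

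Among the brightest piRNA probes of adult islets a set stood apart by array. Of 126 probes with a mean adult level over 7 on the log2 scale and 6 values, 36 were over 2 higher in adult than in P10 islets, 0 were over 2 lower and 90 lay in between. Choosing on adult brightness favours probes higher in adult. Of 95 probes chosen on a mean P10 level over 7 instead, 9 were over 2 higher, 1 was over 2 lower and 85 lay in between. In the fit reported here 1 of the 36 was called, against 35 with array weights, 6 on the deposited values, 36 with P10 1 left out and 0 with P10 2, P10 3, Adult 2 or Adult 3 left out (limma). All 36 were chosen for their difference on these same arrays, so the counts with P10 1 left out or weighted down are no separate test. P10 1 lay nearer to the adult mean than to P10 2 and P10 3 in all 36. Their median levels were 9.02 in P10 1, 3.07 in P10 2 and 3.98 in P10 3, against 10.41, 9.94 and 9.45 in Adult 1, Adult 2 and Adult 3. The 90 other bright probes had medians between 8.34 and 8.87 on all 6 arrays. DQ621930 was at 8.16 in P10 1, 2.09 in P10 2 and 1.80 in P10 3, with an adult mean of 10.03 ± 0.25 (SD). The adult minus P10 difference was 6.01 ± 1.54 (SE; limma adjusted p = 0.059). The adjacent entry DQ621929 was at 9.45, 2.31 and 3.03 in the P10 arrays and at 10.63 ± 0.53 in adult islets.

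P10 1 and Adult 1 lay between the other arrays over the whole set of tested probes as well, and several explanations were tested. Exchanged labels are argued against, since the split of the arrays with P10 1 and Adult 1 exchanged gave 0 calls against 703 (limma; 1429 against 3342 at an unadjusted p below 0.05). A slide effect as the cause for P10 1 is argued against, since P10 1 correlated with Adult 1 by 0.075 more than P10 2 and P10 3 of the same slide did, whereas for Adult 1, which correlated with those arrays by at least 0.046 more than Adult 2 and Adult 3 did, slide and animal cannot be told apart with 1 adult array on that slide. With a plain admixture of adult RNA, P10 1 would lie the same fraction of the way to adult for probes higher and lower in adult. On the linear scale it lay 0.22 of the way for probes higher in adult and 0.53 for probes lower in adult, a difference of -0.315. An error in the scale of P10 1 would move these fractions in opposite directions, so this test cannot decide on an admixture in P10 1. For Adult 1 the corresponding difference of 0.098 also leaves an admixture of P10 RNA open. Differences between litters or animals, in maturation or in the make-up of the islet preparations may also account for the pattern and were not tested. Array brightness stays open as well, since P10 1 and Adult 1 were the brightest arrays of their ages.

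As a check on other arrays, probes called between P10 2 and P10 3 and Adult 2 and Adult 3 (limma) were read on the arrays numbered 1, both on slide 1. Of 1471 probes higher in adult, 83.8% were higher in Adult 1 than in P10 1, with a median of 0.75 on the log2 scale against 2.18 in the choosing arrays. Of 2106 probes lower in adult, 60.3% were lower in Adult 1, with medians of -0.25 and -2.03. Over all 11766 probes, 56.3% were higher in Adult 1.

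The 6 arrays can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split gave 703 calls and the highest of the others 0, so that 1 of the 10 splits reached the real count.

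Probes with neighbouring entry numbers changed alike, which raised the hypothesis that such entries report the same or overlapping RNAs. Over 2740 pairs of tested probes 1 number apart, differences between ages correlated at r = 0.271, a value that none of 10000 random orders reached (one-sided permutation p = 0.0001, the smallest they can give), and the correlation fell to 0.088 at a step of 3. In 38 pairs both probes were called in the same direction, against 5.58 expected over random orders, and in 1 pair in opposite directions. Closeness on the array is argued against as the cause, since pairs printed over 50 rows apart correlated at 0.278. Shared RNA may also make levels and replicate differences correlate, and these gave 0.281 for levels and 0.154 for P10 2 minus P10 3 but only 0.053 for Adult 2 minus Adult 3, which leaves the hypothesis open without the sequences.

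One spot stood out on a single array. DQ750471 was at 7.15 in Adult 1 and between -3.02 and -2.32 on the other 5 arrays, and no other tested probe lay more than 5 on the log2 scale above its next highest array. It was found after the values were seen.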
